A study of Homo sapiens with 12 samples.

How the data were processed

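RNA was measured in RS4:11 and SEM-K2, 2 established cell lines of acute lymphoblastic leukaemia whose leukaemia carries a fusion of the genes KMT2A (MLL) and AFF1 (AF4). Cells of each line were exposed for 6 h to vehicle or to obatoclax, a small molecule designed against the antiapoptotic proteins of the BCL2 family, per the labels. Obatoclax was given at its 72 h EC50, the concentration with an effect midway to the maximum in a 72 h assay, or at 3 times that concentration, written here as 3xEC50. The concentrations, and whether they were the same in both lines, were not given in the sources used here. Each of the 6 conditions had 2 biologic replicates, 12 arrays in all, on the Affymetrix U133 Plus 2 array. The labels do not say that the replicates came from separate passages or days, so p-values measure the spread between these samples, part of which could be technical.

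The authors' deposited values are GCRMA values, per the submitters' processing notes, which name no version of GCRMA. GCRMA corrects background by probe sequence, normalises arrays by quantiles and gives 1 value per probe set. The notes do not state the scale. The deposited values were read as log2, since they ran from 0.64 to 16.22 with array medians between 3.13 and 3.16, the range that GCRMA gives on the log2 scale. No value was missing and no pair of arrays held identical values. Scanner files were not used here. No count or depth lies behind an array value, so the number of arrays limits the precision.

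Of 54675 probe sets, 41097 had exactly 1 gene symbol in the platform annotation, 1801 had several and 11777 were not listed there. Probe sets with several symbols were given no name. Entrez identifiers of 41043 probe sets matched a RefSeq gene table of the human assembly GRCh38.p14, 54 probe sets kept the annotation's own symbol, and no symbol changed. The 62 control probe sets were left out of the tests. Where a gene had several probe sets, as 10523 of 19775 genes did, the probe set with the highest mean over all 12 arrays stood for it. Genes were kept where that probe set exceeded 4 on the log2 scale in at least 2 of the 12 arrays, which left 10561 genes. Of these, 675 rested on a probe set ending in _x_at and 3288 on one ending in _s_at, whose probes can match other transcripts or genes. A mean under 4 was read as not above this floor. A fold against such a group was computed from the floor and is given as a lower bound.

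Changes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8). 1 model over all 12 arrays held 6 group means, with 6 residual and 3.27 prior degrees of freedom. Contrasts were each dose against its line's vehicle, 3xEC50 against EC50 within a line, the difference between the lines in each response (SEM-K2 minus RS4:11), and vehicle against vehicle (SEM-K2 minus RS4:11). P-values were adjusted by the Benjamini-Hochberg method within a contrast and a gene was called at an adjusted p under 0.05. Chance alone would give about 528 genes with an unadjusted p under 0.05 in a contrast. The symbol ± marks the standard error (SE) of a log2 change, and the SD of 2 replicates where so stated. All arrays shared 1 estimate of the spread.

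30 gene lists with 741 genes, 560 of them among the genes tested, were fixed before the data were examined, as were the comparisons, the tests, the thresholds, the alternatives and the rule for the genes to name. The lists covered cholesterol and fatty acid synthesis, the integrated stress response, endoplasmic reticulum chaperones, heat shock, the NRF2 response, metallothioneins, hypoxia and glycolysis, autophagy, lysosome, both arms of the BCL2 family, caspases and death receptors, necroptosis, the mTOR pathway, p53 targets, NF-kappaB targets, immediate early genes, interferon-stimulated genes, ribosome biogenesis, ribosomal proteins, DNA replication, mitosis, oxidative phosphorylation, B cell precursor markers, MLL fusion targets, and markers of myeloid, T and NK, erythroid and megakaryocyte, and fibroblast and epithelial cells. Each list was tested with limma's camera against the other genes at a preset correlation of 0.01 between genes, adjusted over the 30 lists within a contrast. Camera was repeated with a correlation estimated from the data. Fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, was a further alternative. List members were counted over all genes tested and adjusted over the list alone. The list tests of the difference between the lines at EC50 were added after the data were examined.

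The rule named, where both treated arrays lay beyond both control arrays, the called genes with the largest rise and fall by log2 value, without the floor (8 and 8 per 3xEC50 contrast, 5 and 5 per EC50 contrast and per difference between lines, 3 and 3 between doses, 6 and 6 between vehicles). It added up to 3 called members of each list per 3xEC50 contrast, or the 1 with the smallest p where none was called, and BCL2, BCL2L1, BCL2L2, MCL1, BAX, BAK1, KMT2A and AFF1. Other genes are said to be chosen after their values were seen, except list members named because they passed when adjusted over the list alone.

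The labels give the replicates numbers but not what a number stands for. Deviations from the group means of equally numbered arrays correlated positively in all 15 pairs of groups (r across genes 0.191 to 0.601, 6 pairs within a line at 0.350 or more), so the numbers were taken to pair the arrays. A fit with the replicate number as a block over all arrays, and one with a block within each line, were run beside the fit without a block. The other alternatives were eBayes with trend and robust settings, no floor, a floor of 6, another median or quantile scaling, the mean of a gene's probe sets, leaving out _x_at probe sets, every probe set on its own, only the arrays compared, an adjusted p under 0.01, a 2-fold minimum, and leaving out each array in turn. Since both doses of a line share vehicle arrays, their correlation was set beside 100 simulated pairs of unchanged groups against those arrays. The same simulation for genes chosen at 3xEC50, and the ranks counted from the floor, were added after the data were examined.

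The procedure was tested on simulated data made from the real spread, with 200 genes changed in each of 10 draws. In the simulated contrast of SEM-K2 3xEC50 against vehicle, 56.9% of genes changed by 1 on the log2 scale, 91.2% of those changed by 1.5 and 97.6% of those changed by 2 were called, and 76 of 103250 unchanged genes were. For the simulated difference between the lines at 3xEC50 these shares were 13.9%, 57.5% and 83.0%. A simulated list of 36 genes shifted by 0.5 in RS4:11 at 3xEC50 was called in all 10 draws, and 0 of 290 other lists were called by camera. The simulated genes varied independently and shared no replicate effect, so these list results do not cover correlated genes. Each simulated gene also had the same spread in every group. In the data the SD across genes of the difference between replicates was 0.512 in SEM-K2 at 3xEC50 and 0.327 to 0.439 in the other groups. The shares of genes called do not cover such unequal spread. Figures were drawn with matplotlib 3.10.9.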

Results

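Gene expression was measured in 12 samples of RS4:11 and SEM-K2, cell lines of acute lymphoblastic leukaemia with a KMT2A-AFF1 fusion, after 6 h with vehicle, obatoclax at its 72 h EC50 or obatoclax at 3xEC50. Each of the 6 groups held 2 replicates. Between 41.6% and 42.7% of the probe sets of an array lay above 4 on the log2 scale. The cell line accounted for most of the variance, with 80.5% on the principal component that separated the lines. The arrays of a group correlated at 0.991 to 0.996 in 5 groups and at 0.987 in SEM-K2 at 3xEC50, with a median of 0.994. Arrays of 1 line with the same replicate number but another treatment had a median of 0.996. The second principal component, with 6.4% of the variance, was positive on all arrays numbered 1 and negative on all numbered 2. Unless the replicate block is named, counts, SEs and p-values below come from the fit without it. SEM-K2 3xEC50 replicate 2 stood apart in the signs of RNA quality. The log2 difference between the 3' and 5' control probe sets of ACTB, a cytoskeletal actin, was 1.97 on this array and 0.87 to 1.23 on the other 11. That of GAPDH, a glycolytic enzyme, was 0.61 on it and 0.08 to 0.30 on the others. RS4:11 vehicle replicate 1 had more 18S ribosomal RNA signal than the others, at 9.85 for the 3' control probe set, where no other array exceeded 6.98.

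**Figure D1:**
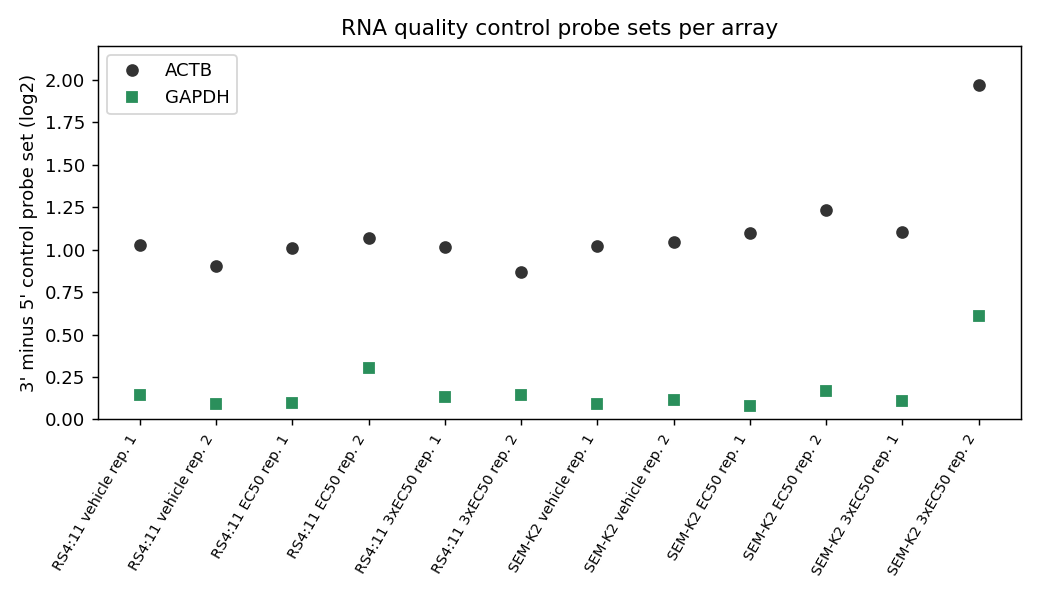
Log2 difference between the 3' and 5' control probe sets of ACTB and GAPDH on each of the 12 arrays, 1 point per array. SEM-K2 3xEC50 replicate 2 lies apart at 1.97 for ACTB and 0.61 for GAPDH.

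The comparison of SEM-K2 at 3xEC50 with vehicle asks what 6 h of the higher dose did to the transcripts of this line. TNFAIP3 and NFKBIA, which restrain NF-kappaB, the lysosome list genes FLCN and FNIP2 and the B cell gene BACH2 rose, while the guidance ligand gene SEMA3A and the homeobox gene DLX2 fell. The scaffold gene KANK1, which regulates the actin cytoskeleton, went from 2.54 ± 0.00 to 6.99 ± 0.29 (log2, SD, n = 2), a rise of at least 7.93-fold over the floor. TNFAIP3, which encodes the feedback inhibitor A20 of NF-kappaB, rose by 2.83 ± 0.41 on the log2 scale. FLCN, the folliculin gene that acts on mTORC1 and TFEB at the lysosome, rose by 1.38 ± 0.15. BACH2, a transcriptional repressor of the B lineage, rose by 2.01 ± 0.17. In all, 66 genes rose and 21 fell, 74 of these 87 by at least 2-fold.

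The rule named 8 rises by log2 value, without regard to the floor. KANK1 had an adjusted p of 7.21e-06. Next by log2 value were STARD13 (3.97 ± 0.36, adjusted p = 0.00175) and ENPP2, which encodes the lysophospholipase D autotaxin (3.82 ± 0.30, adjusted p = 6.62e-04). The tyrosine phosphatase gene PTPRE (3.12 ± 0.33, adjusted p = 0.00476) and CD1A, a lipid antigen-presenting molecule (3.12 ± 0.22, adjusted p = 4.99e-04), followed. The collagen gene COL15A1 rose by 2.89 ± 0.52 (adjusted p = 0.0446), the receptor gene GPR18 by 2.85 ± 0.38 (adjusted p = 0.0135) and TNFAIP3 with an adjusted p of 0.0167. KANK1, STARD13, ENPP2, CD1A and COL15A1 lay below the floor in vehicle, so their rises are at least 7.93-fold, 6.75-fold, 7.22-fold, 4.04-fold and 2.69-fold. Counted from the floor, PTPRE had the largest rise of the called genes, KANK1 ranked 2, CD1A ranked 12 and COL15A1 ranked 30. The other probe sets were smaller for STARD13, at 2.18 for the lowest, and for PTPRE, at 0.01. The largest falls by log2 value were in SEMA3A, a guidance ligand (-3.04 ± 0.34, adjusted p = 0.00591), KLHL14 (-2.96 ± 0.37, adjusted p = 0.00889), and the homeobox gene DLX2 (-2.17 ± 0.15, adjusted p = 4.99e-04). DLX2 ended below the floor, a fall of at least 1.98-fold that ranked 17 when counted from the floor. KANK1, STARD13, ENPP2, CD1A, COL15A1, SEMA3A, MFAP3L and DLX2 lay below the floor on all RS4:11 arrays, which enter the shared estimate of the spread. There DLX2 ran only from 2.55 to 2.58, COL15A1 from 2.51 to 2.55 and CD1A from 2.52 to 2.62. The p-values of such genes may therefore be too small. MFAP3L (-2.02), the dNTP hydrolase gene SAMHD1 (-1.88), the Toll-like receptor gene TLR10 (-1.75), the metalloprotease gene ADAMTS17 (-1.69) and the adaptor gene APBA1 (-1.65) also fell, with adjusted p-values from 0.0146 to 0.049. The highest probe set of APBA1 showed -0.32.

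**Figure D2:**
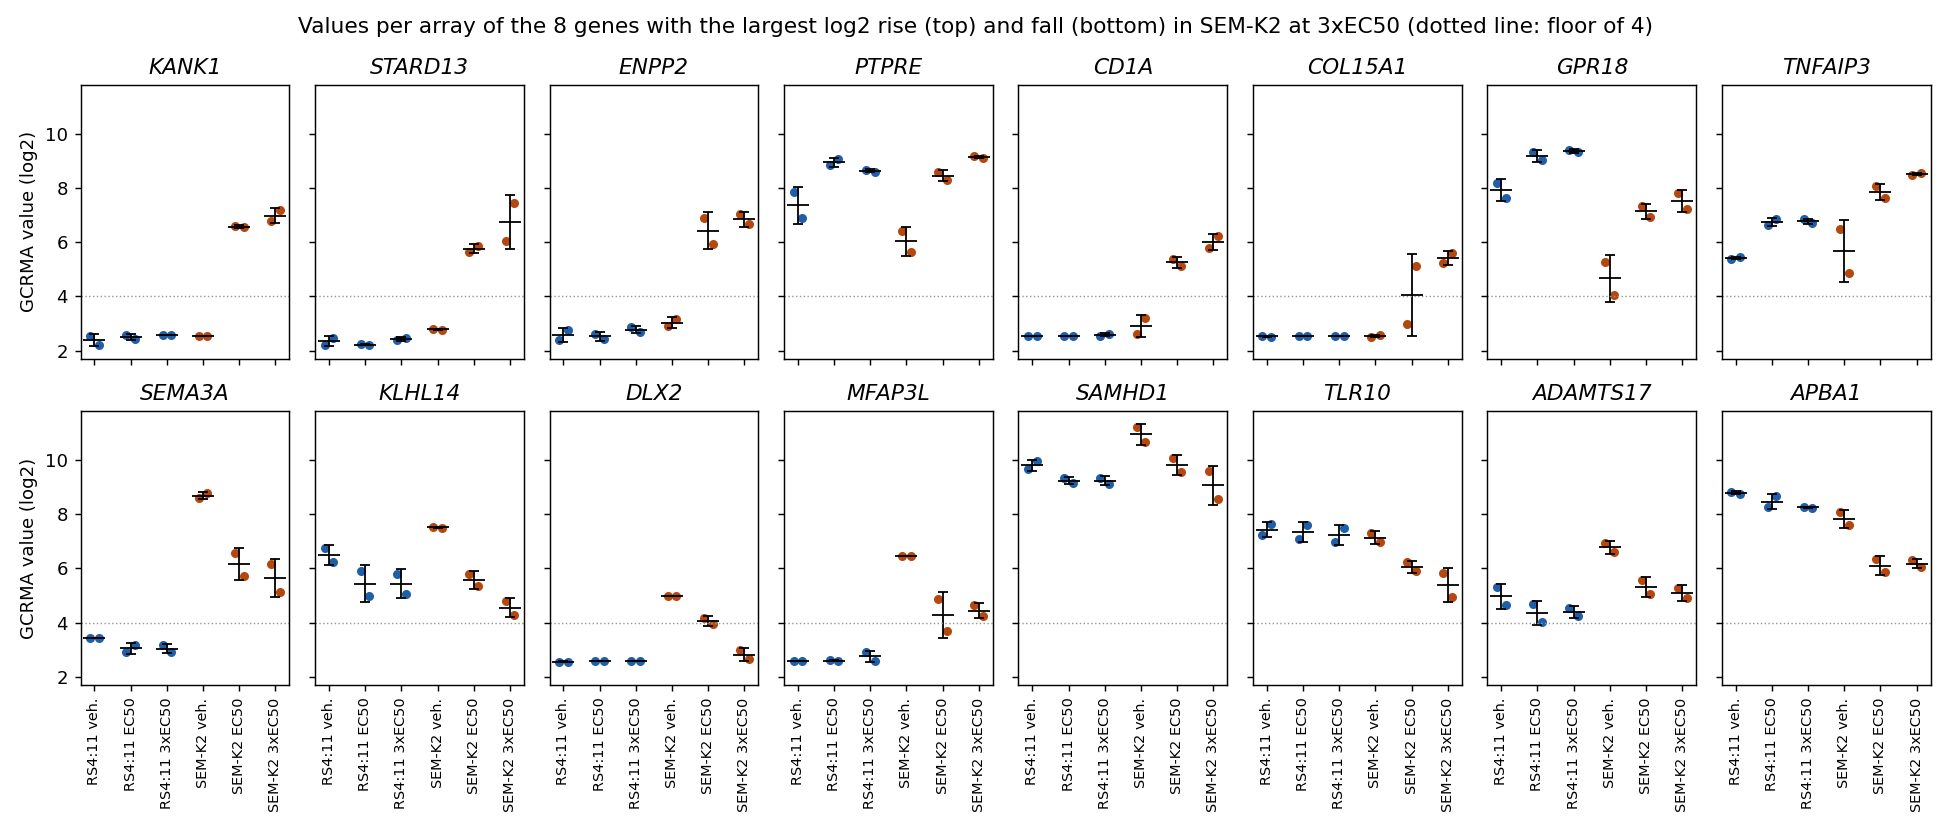
Log2 values on each array of the 8 genes with the largest log2 rise and the 8 with the largest log2 fall in SEM-K2 at 3xEC50, before the floor is applied, with the mean and SD of 2 replicates per group; the dotted line is the floor of 4. KANK1 lay at 2.54 in SEM-K2 vehicle and at 6.99 at 3xEC50, and stayed below the floor in RS4:11.

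By list, the lysosome genes had the smallest camera p in SEM-K2 at 3xEC50. Of 29 members 28 lay above 0, with a median of 0.49, and camera gave an adjusted p of 2.93e-10 (adjusted p = 0.125 with an estimated correlation). FLCN, its binding partner FNIP2 (1.04 ± 0.14) and the sialidase gene NEU1 (1.51 ± 0.28) rose over all genes, and 11 members, among them the cholesterol exporter gene NPC2 (1.22) and the cathepsin gene CTSB (0.77), rose when adjusted over the list alone. The call on NEU1 was close to the threshold (adjusted p = 0.049). RRAGC of the mTOR pathway, a GTPase that passes amino acid signals to mTORC1, rose as well (1.03 ± 0.17, adjusted p = 0.0353), while that list did not shift (14 of 25 above 0, adjusted p = 0.983). The 8 NF-kappaB targets had a median of 1.06 and an adjusted p of 2.28e-04 (adjusted p = 0.141 with an estimated correlation). Of these, TNFAIP3, the dendritic and B cell activation marker CD83 (1.76 ± 0.23) and NFKBIA, the inhibitor that holds NF-kappaB in the cytoplasm (1.42 ± 0.24), rose over all genes, and the same 3 when adjusted over the list alone. Without SEM-K2 3xEC50 replicate 1 the adjusted p of this list was 0.0726.

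Interferon-stimulated genes shifted up in SEM-K2 at 3xEC50, with a median of 0.44 over 12 genes and an adjusted p of 0.00965 (adjusted p = 0.658 with an estimated correlation). OAS3, a sensor of double-stranded RNA, rose over all genes (0.95 ± 0.14, adjusted p = 0.016) and IFIH1, another such sensor, when adjusted over the list alone (1.17). Cholesterol genes had a median of 0.42, with 15 of 19 above 0, and an adjusted p of 0.00965 (adjusted p = 0.735 with an estimated correlation). Of these, 0 were called over all genes by limma, 5 had an unadjusted p under 0.05, and the synthesis enzyme gene SQLE rose when adjusted over the list alone (0.75). With the replicate block 3 cholesterol genes rose over all genes. Autophagy genes had a median of 0.19 and an adjusted p of 0.0256 (adjusted p = 0.658 with an estimated correlation). Among them the cargo receptor gene SQSTM1 rose (1.27 ± 0.20, adjusted p = 0.0266), although its lowest probe set changed by 0.17. Ribosome biogenesis genes shifted down, with 19 of 21 below 0, a median of -0.41 and an adjusted p of 2.01e-08 (adjusted p = 0.658 with an estimated correlation, and 0.0484 when that fit held the replicate block). Over all genes 0 of them were called by limma, 8 had an unadjusted p under 0.05, WDR43 fell when adjusted over the list alone (-0.67), and 2 fell over all genes with the replicate block.

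Smaller shifts in SEM-K2 at 3xEC50 concerned heat shock genes (median -0.11, 14 of 15 below 0, adjusted p = 0.0387) and metallothioneins (median -0.21, 6 of 8 below 0, adjusted p = 0.0350). With an estimated correlation these gave adjusted p = 0.735 and adjusted p = 0.658. No member of either was called by limma over all genes or over its list alone, and 1 and 2 had an unadjusted p under 0.05. With the replicate block metallothioneins gave an adjusted p of 0.0553, B cell precursor markers 0.0199 (0.0760 without it) and hypoxia and glycolysis genes 0.00688 (0.190 without it). With an estimated correlation and the block, the B cell and hypoxia lists gave adjusted p = 0.410 and adjusted p = 0.612. BACH2 was the B cell gene called over all genes (adjusted p = 0.00105), and the surface receptor genes CD22 (0.91) and CD72 rose when adjusted over that list alone. Integrated stress response genes were split. Their median was -0.11 and their mean 0.02, camera gave an adjusted p of 0.455 in the direction down, and PPP1R15A, which restarts translation after stress, rose (1.51 ± 0.25, adjusted p = 0.0312). DDIT3, the CHOP gene, rose when adjusted over the list alone (1.15 ± 0.22), and 14 of 36 members lay above 0.

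Single arrays moved these results in SEM-K2 at 3xEC50. The count of 87 genes became 14 without vehicle replicate 2 and 18 without 3xEC50 replicate 2, the array with the high 3' to 5' differences. It became 169 without vehicle replicate 1 (142 up and 27 down). Without 3xEC50 replicate 1, where the dose rests on the array with the high 3' to 5' differences, it became 151, and falls outnumbered rises (55 up and 96 down). It was 51 to 55 without any RS4:11 vehicle, RS4:11 EC50 or SEM-K2 EC50 array, and 39 without either RS4:11 3xEC50 array. The replicate block gave 220 genes, and 299 when fitted within each line. A fit of only the SEM-K2 vehicle and 3xEC50 arrays, with fewer residual degrees of freedom, called none of the 26 named genes (KANK1 adjusted p = 0.111). Without any 1 array, 7 of the 26 named genes stayed called: KANK1, STARD13, ENPP2, PTPRE, CD1A, DLX2 and BACH2. Without 3xEC50 replicate 1 the list calls were lost for cholesterol (adjusted p = 0.844), heat shock (0.553), metallothioneins (0.274), autophagy (0.165), NF-kappaB targets (0.0726) and interferon-stimulated genes (0.453). Without vehicle replicate 2 they were lost for cholesterol (0.123), heat shock (0.610), autophagy (0.0598) and interferon-stimulated genes (0.123), and without vehicle replicate 1 for metallothioneins (0.216). No list call was lost without 3xEC50 replicate 2, and the lysosome and ribosome biogenesis calls held without any 1 array. The ribosome biogenesis median fell to -0.19 without 3xEC50 replicate 1 (adjusted p = 0.0275), and that of heat shock genes became -0.23 without vehicle replicate 1 and -0.25 without 3xEC50 replicate 2. With the mean of a gene's probe sets, the calls on COL15A1, SAMHD1, TLR10, ADAMTS17, APBA1, SQSTM1, NEU1, FLCN, FNIP2, RRAGC, NFKBIA and OAS3 were lost, and without _x_at probe sets those on SAMHD1 (0.165) and TLR10 (0.149).

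The comparison of SEM-K2 at EC50 with vehicle asks what the lower dose did. KANK1 rose by 4.04 ± 0.17 on the log2 scale, to 6.58 ± 0.05 (SD, n = 2), at least 5.98-fold over the floor. ENPP2 rose by 3.39 ± 0.30, at least 5.39-fold. The guidance ligand gene SEMA3A fell by 2.54 ± 0.34. FLCN (1.10 ± 0.15) and BACH2 (1.32 ± 0.17) rose. In all, 12 genes rose and 6 fell, all 18 by at least 2-fold.

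The named rises in SEM-K2 at EC50 were KANK1 (adjusted p = 1.73e-05), ENPP2 (adjusted p = 0.00369), STARD13 (2.98, adjusted p = 0.0232), PTPRE (2.43, adjusted p = 0.0306) and CD1A (2.36, adjusted p = 0.00369). STARD13 and CD1A, like KANK1 and ENPP2, lay below the floor in vehicle, and rose at least 3.40-fold and 2.39-fold. The named falls were SEMA3A (adjusted p = 0.0306), MFAP3L (-2.18, adjusted p = 0.0428), APBA1 (-1.73, adjusted p = 0.0306), the adenylate cyclase gene ADCY6 (-1.24 ± 0.17, adjusted p = 0.0306) and the circadian clock gene PER3 (-1.12 ± 0.16, adjusted p = 0.0346). Lysosome genes shifted up, with 28 of 29 above 0, a median of 0.30 and an adjusted p of 8.64e-09 (adjusted p = 0.120 with an estimated correlation). FLCN was called over all genes (adjusted p = 0.0332), and FLCN, FNIP2, NEU1 and RRAGD rose when adjusted over the list alone. NF-kappaB targets had a median of 0.71 and an adjusted p of 1.12e-04 (adjusted p = 0.120 with an estimated correlation). Of them TNFAIP3 (2.17), CD83 (1.38) and NFKBIA (0.80) rose when adjusted over the list alone. Over all genes limma called 0, with 4 at an unadjusted p under 0.05 and 1 called with the replicate block. Interferon-stimulated genes had a median of 0.47 and an adjusted p of 1.70e-04 (adjusted p = 0.591 with an estimated correlation), and IFIH1 (0.89), OAS2 (0.73) and OAS3 (0.61) rose when adjusted over the list alone. Over all genes limma called 0 of them, 4 had an unadjusted p under 0.05, and the replicate block added none. B cell precursor markers had a median of 0.35 and an adjusted p of 0.0364 (adjusted p = 0.746 with an estimated correlation), with BACH2 called over all genes (adjusted p = 0.0285) and CD72 (1.15) when adjusted over the list alone. Ribosome biogenesis genes had a median of -0.28, with 19 of 21 below 0, and an adjusted p of 4.12e-07 (adjusted p = 0.746 with an estimated correlation). With the replicate block, cholesterol genes (adjusted p = 0.00978, 0.0711 without it), hypoxia and glycolysis genes (0.00241, 0.204 without it) and immediate early genes (0.0113, 0.0711 without it) also shifted up. With an estimated correlation and the block these gave adjusted p = 0.505, 0.505 and 0.517.

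The count of 18 in SEM-K2 at EC50 became 46 with the replicate block and 70 with the block within each line. It was 3 without EC50 replicate 2, 4 without vehicle replicate 2, 7 without either RS4:11 3xEC50 array, 8 without EC50 replicate 1 and 9 without any RS4:11 vehicle or EC50 array. KANK1, ENPP2 and CD1A stayed called without any 1 array. With trend and robust settings the calls on ADCY6 (adjusted p = 0.0574) and PER3 (0.0892) were lost. With the mean of a gene's probe sets those on PTPRE (0.91, adjusted p = 0.130) and APBA1 (-1.07, adjusted p = 0.155) were lost. The interferon call was lost without vehicle replicate 2 (adjusted p = 0.0672). Ribosome biogenesis was lost without EC50 replicate 1 (0.0706) or vehicle replicate 2 (0.0672), and B cell precursor markers without vehicle replicate 1 (0.0695), EC50 replicate 1 (0.434) or vehicle replicate 2 (0.0887). Of the calls that held, lysosome genes (0.19) and NF-kappaB targets (0.45) had medians over 1.5 times smaller without vehicle replicate 2, and interferon-stimulated genes (0.32) without EC50 replicate 1. Larger ones by over 1.5 times came from ribosome biogenesis without vehicle replicate 1 (-0.45) or EC50 replicate 2 (-0.47) and from B cell precursor markers without EC50 replicate 2 (0.54).

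The comparison of RS4:11 at 3xEC50 with vehicle asks what the higher dose did to the other line. Genes of the integrated stress response, which ATF4 and CHOP drive and which supply amino acids and charge transfer RNAs, fell as a group at the preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.0519). Chaperones of the endoplasmic reticulum fell with both (adjusted p = 0.0374 with an estimated correlation), but not when the latter fit held the replicate block (adjusted p = 0.0918). The cystine transporter gene SLC7A11 went from 7.25 ± 0.53 to 5.20 ± 0.72 (log2, SD, n = 2), and the chaperone gene HSPA5 (BiP) from 12.57 ± 0.07 to 11.66 ± 0.33. Lysosome genes, interferon-stimulated genes and B cell precursor markers shifted up (adjusted p = 0.215, 0.520 and 0.520 with an estimated correlation). Limma called 0 single genes over all genes, where 518 had an unadjusted p under 0.05 and the smallest adjusted p was 0.245.

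Of the 36 integrated stress response genes, 29 lay below 0 in RS4:11 at 3xEC50, with a median of -0.45. Camera gave an adjusted p of 1.05e-18 (adjusted p = 0.0519 with an estimated correlation). Adjusted over the list alone, 18 members fell. These included SLC7A11 (-2.05 ± 0.52), SESN2 (-1.40 ± 0.43), the serine synthesis gene PSAT1 (-1.07 ± 0.24), the proline synthesis gene PYCR1 (-0.83 ± 0.15), the transfer RNA synthetase genes WARS1 (-1.08), CARS1 (-0.86) and GARS1 (-0.79), the amino acid transporter gene SLC7A5 (-1.03), and CEBPB (-0.97). Over all genes 0 members were called by limma, with 20 at an unadjusted p under 0.05 and none called with the replicate block. Of the 23 endoplasmic reticulum chaperone genes 20 lay below 0, with a median of -0.34 and an adjusted p of 9.68e-10 (adjusted p = 0.0374 with an estimated correlation, and 0.0918, no longer past the threshold, when that fit held the replicate block). Adjusted over the list alone 9 fell, among them SDF2L1 (-0.97 ± 0.20), MANF (-0.92 ± 0.17), HSPA5 (-0.91 ± 0.22) and HSP90B1 (-0.83), while ERN1, the sensor IRE1, rose (0.53), by at least 1.12-fold from below the floor. Ribosome biogenesis genes shifted down, with 20 of 21 below 0, a median of -0.43 and an adjusted p of 3.57e-09 (adjusted p = 0.547 with an estimated correlation, and 0.0391 when that fit held the replicate block). The member with the smallest p, RRS1, changed by -0.61 (adjusted p = 0.747).

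Lysosome genes shifted up in RS4:11 at 3xEC50, with 24 of 29 above 0, a median of 0.13 and an adjusted p of 2.06e-05 (adjusted p = 0.215 with an estimated correlation). FLCN (0.95 ± 0.15) and FNIP2 (0.84 ± 0.14) rose when adjusted over the list alone. Interferon-stimulated genes had a median of 0.39, with 10 of 12 above 0, and an adjusted p of 9.06e-04 (adjusted p = 0.520 with an estimated correlation). B cell precursor markers had a median of 0.38, with 20 of 22 above 0, and an adjusted p of 5.04e-04 (adjusted p = 0.520 with an estimated correlation), and BACH2 rose when adjusted over the list alone (0.87 ± 0.17). Mitosis genes had a median of 0.28, with 23 of 24 above 0, and an adjusted p of 0.0167 (adjusted p = 0.742 with an estimated correlation), and no member had an unadjusted p under 0.05. Autophagy genes had a median of 0.12 and an adjusted p of 0.0267 (adjusted p = 0.684 with an estimated correlation). The p53 target TP53INP1, which promotes autophagy and cell death, rose when adjusted over its list alone (0.98 ± 0.19), from below the floor and thus at least 1.12-fold. The MLL fusion target EYA1 fell when adjusted over its list alone (-1.46 ± 0.24), but did not pass over all genes by limma (adjusted p = 0.245). It ended below the floor, a fall of at least 2.74-fold.

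Without 3xEC50 replicate 1 the mitosis genes had a median of -0.01 in RS4:11 at 3xEC50 (adjusted p = 0.733), and without vehicle replicate 2 one of -0.19 (adjusted p = 0.0353), opposite to the shift with all arrays. The autophagy call was lost without vehicle replicate 1 (0.0556), vehicle replicate 2 (0.168) or 3xEC50 replicate 2 (0.120). Mitosis genes had 0.73 without vehicle replicate 1 and 0.53 without 3xEC50 replicate 2. The other list calls in RS4:11 at 3xEC50 held without any 1 array, but some medians moved by over 1.5 times. Without 3xEC50 replicate 1, chaperones had -0.21, ribosome biogenesis -0.23 and lysosome genes 0.20. Without vehicle replicate 2, ribosome biogenesis had -0.24, B cell precursor markers 0.20 and interferon-stimulated genes 0.26. The count of genes was 1 without RS4:11 vehicle replicate 1 or either SEM-K2 vehicle array and 0 otherwise. With the replicate block it was 0, with 1031 genes at an unadjusted p under 0.05. The mean of a gene's probe sets gave 1 gene and every probe set on its own gave 4 probe sets.

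**Figure D3:**
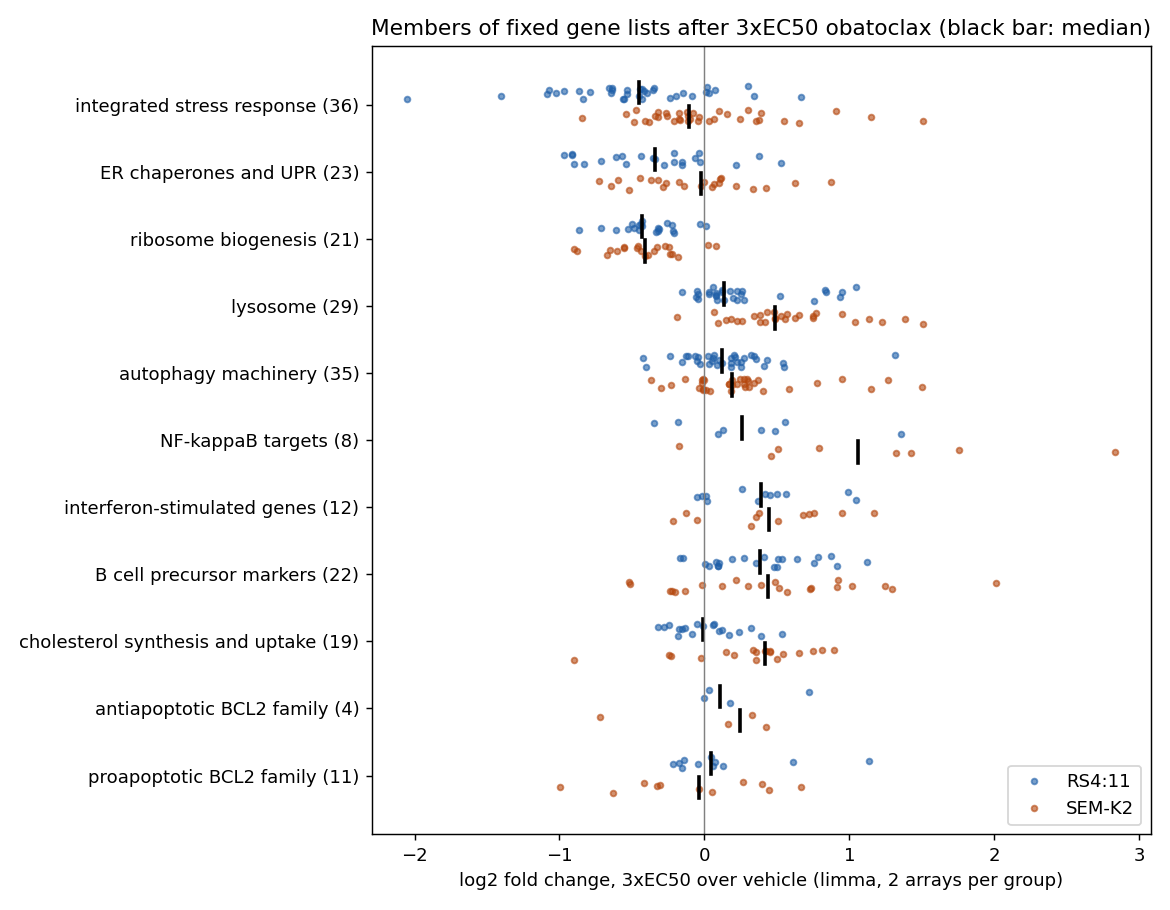
Log2 changes at 3xEC50 against vehicle of the members of 11 gene lists in RS4:11 and SEM-K2, 1 point per gene, with a bar at each list's median. Integrated stress response genes have a median of -0.45 in RS4:11 and -0.11 in SEM-K2, and lysosome genes of 0.13 and 0.49.

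The comparison of RS4:11 at EC50 with vehicle asks what the lower dose did to this line. Integrated stress response genes (30 of 36 below 0, median -0.41) and endoplasmic reticulum chaperone genes (20 of 23 below 0, median -0.25) fell as groups at this dose too. Camera gave adjusted p-values of 9.58e-20 (adjusted p = 0.0454 with an estimated correlation) and 3.79e-09 (adjusted p = 0.0442 with an estimated correlation). When the fits with an estimated correlation held the replicate block, both calls were lost (adjusted p = 0.124 and 0.0961). Adjusted over the lists alone, 13 and 5 members fell, with SLC7A11 (-2.12), PSAT1 (-1.01), HSPA5 (-0.84) and SDF2L1 (-0.83) among them. Lysosome genes shifted up (26 of 29 above 0, median 0.17, adjusted p = 4.71e-06, adjusted p = 0.168 with an estimated correlation), with FLCN (1.06) and FNIP2 (0.86) up when adjusted over the list alone. Interferon-stimulated genes (median 0.31, adjusted p = 2.22e-04, adjusted p = 0.482 with an estimated correlation) and B cell precursor markers (median 0.34, adjusted p = 0.00162, adjusted p = 0.597 with an estimated correlation) also shifted up. BACH2 rose when adjusted over the latter list alone (0.84). Autophagy genes had a median of 0.12 and an adjusted p of 0.0323 (adjusted p = 0.637 with an estimated correlation), with the kinase gene ULK2 up when adjusted over the list alone (0.77, at least 1.49-fold from below the floor). All 21 ribosome biogenesis genes lay below 0 (median -0.35, adjusted p = 6.29e-08, adjusted p = 0.597 with an estimated correlation). TP53INP1 rose by 1.17 when adjusted over the p53 list alone, at least 1.28-fold from below the floor.

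Over all genes limma called 0 in RS4:11 at EC50, with 444 at an unadjusted p under 0.05 and a smallest adjusted p of 0.224. The replicate block called 0 (843 at an unadjusted p under 0.05), no floor 2, the mean of probe sets 1 and every probe set on its own 1. Without RS4:11 vehicle replicate 1, 3 genes were called, and without either SEM-K2 vehicle array 1 was. The autophagy call was lost without vehicle replicate 2 (adjusted p = 0.245) or EC50 replicate 2 (0.429), and the B cell call without EC50 replicate 1 (0.102) or vehicle replicate 2 (0.0896). Of the calls that held, ribosome biogenesis had a median of -0.18 without EC50 replicate 1 and -0.21 without vehicle replicate 2. Interferon-stimulated genes had 0.21 without vehicle replicate 2 and 0.47 without vehicle replicate 1, lysosome genes 0.26 without the latter, and autophagy genes 0.19 without EC50 replicate 1. Mitosis genes (median 0.20, adjusted p = 0.0927) passed with the replicate block (adjusted p = 0.00766, and adjusted p = 0.738 with an estimated correlation and the block). Without vehicle replicate 2 they passed in the other direction, with a median of -0.23.

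The comparison of both doses within a line asks whether 3xEC50 did more than EC50. In SEM-K2, all 87 genes called at 3xEC50 had the same direction at EC50, and 84 had the larger change at 3xEC50, with a median size of 1.42 against 1.09. These genes were chosen at 3xEC50, which favours larger values there, and both doses share the vehicle arrays. In 100 simulations without any change, 87 genes chosen in this way gave on average 83.0 with the same direction (78 to 87) and 82.9 with the larger change at 3xEC50 (78 to 87). Neither count lay outside what no change at either dose gives. Equal changes at both doses were not simulated, so these counts cannot say whether 3xEC50 did more than EC50. The median sizes in these simulations averaged 0.63 at 3xEC50 and 0.32 at EC50. In a direct contrast, limma called 0 genes in SEM-K2 (234 at an unadjusted p under 0.05) and 0 in RS4:11 (85 at an unadjusted p under 0.05). The replicate block also called 0 in each (533 and 169 at an unadjusted p under 0.05), no floor called 3 and 2, and quantile scaling 1 in SEM-K2. Without SEM-K2 3xEC50 replicate 1, 36 genes were called in SEM-K2, 5 up and 31 down, and without EC50 replicate 2, 1 was. The 18 genes called at EC50 in SEM-K2 were all among those called at 3xEC50 (12 rises and 6 falls, where independent lists would share 0.0750 and 0.0119). Across genes, which are not independent replicates, the changes at both doses correlated at 0.770 in SEM-K2 and 0.783 in RS4:11, and unchanged groups against the same vehicle arrays gave 0.501 and 0.499. The covariances were 0.0920 against a simulated 0.0359 in SEM-K2 and 0.0592 against 0.0358 in RS4:11. With 2 vehicle arrays no split left 2 in each part, so none was made, and part of the excess in overlap may come from the shared controls.

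The comparison of the lines asks where their responses to equal multiples of the EC50 differed. KANK1 rose more in SEM-K2 at both doses, by 3.92 ± 0.25 at EC50 (adjusted p = 5.28e-04) and 4.24 ± 0.25 at 3xEC50 (adjusted p = 2.58e-04). At 3xEC50 ENPP2 (3.62 ± 0.42, adjusted p = 0.026) and CD1A (3.06 ± 0.31, adjusted p = 0.0103) also rose more in SEM-K2 and DLX2 fell more (-2.18 ± 0.22, adjusted p = 0.0103). All 4 lay below the floor on the RS4:11 vehicle and 3xEC50 arrays, where a fall, such as that of DLX2, could not show. KANK1, ENPP2 and CD1A also lay below it in SEM-K2 vehicle, so the sizes of these differences rest on values below the floor. Part of the spread behind the p-values of all 4 rests on such values too. Limma called 1 gene at EC50 and these 4 at 3xEC50. With the replicate block STARD13, below the floor in RS4:11 and SEM-K2 vehicle, joined them (3.89, adjusted p = 0.0243), and with the block within each line 2 and 7 genes were called.

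Integrated stress response genes differed between the lines at 3xEC50, with 32 of 36 higher in SEM-K2 relative to RS4:11, a median difference of 0.50 and an adjusted p of 4.33e-10 (adjusted p = 0.213 with an estimated correlation). Adjusted over the list alone, the stress effector genes ATF3 (1.47), CEBPB (1.36), DDIT3 (1.35) and TRIB3 (1.08) differed upwards and the cystathionine synthase gene CBS downwards (-1.51, with all RS4:11 means and that of SEM-K2 at 3xEC50 below the floor). Endoplasmic reticulum chaperones (median 0.27, adjusted p = 0.00274, adjusted p = 0.222 with an estimated correlation), NF-kappaB targets (1.08, adjusted p = 9.89e-04, adjusted p = 0.213 with an estimated correlation), lysosome genes (0.28, adjusted p = 9.89e-04, adjusted p = 0.273 with an estimated correlation) and cholesterol genes (0.36, adjusted p = 0.00303, adjusted p = 0.833 with an estimated correlation) differed in the same direction. Metallothioneins (-0.38, adjusted p = 9.89e-04, adjusted p = 0.262 with an estimated correlation) and oxidative phosphorylation genes (-0.08, adjusted p = 0.00416, adjusted p = 0.833 with an estimated correlation) differed in the other. CD83 (1.37), NFKBIA (1.33), SQSTM1 (1.21), OAS3 (0.94), BACH2 (1.14) and EYA1 (2.49 ± 0.34) differed when adjusted over their lists alone. Over all genes EYA1 had an adjusted p of 0.0625. At EC50, integrated stress response genes (median 0.41, adjusted p = 5.80e-15, adjusted p = 0.118 with an estimated correlation), endoplasmic reticulum chaperones (0.21, adjusted p = 1.15e-04, adjusted p = 0.118 with an estimated correlation) and NF-kappaB targets (0.58, adjusted p = 0.00281, adjusted p = 0.181 with an estimated correlation) differed upwards. With the replicate block, hypoxia and glycolysis genes at 3xEC50 (adjusted p = 0.00233, 0.0708 without it), and cholesterol (0.0114, 0.101 without it) and immediate early genes at EC50 (0.0431, 0.204 without it), differed as well. With an estimated correlation and the block these gave adjusted p = 0.597, 0.706 and 0.706.

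Of the differences between the lines, the integrated stress response calls at both doses and the chaperone call at EC50 held without any 1 array. Without SEM-K2 3xEC50 replicate 1, the calls at 3xEC50 were lost for cholesterol (adjusted p = 0.695), chaperones, lysosome and NF-kappaB targets (each 0.168), metallothioneins (0.130) and oxidative phosphorylation (0.569). The cholesterol call was also lost without RS4:11 3xEC50 replicate 2 (0.0864) or SEM-K2 vehicle replicate 2 (0.114). The oxidative phosphorylation call was also lost without RS4:11 vehicle replicate 1 (0.184), SEM-K2 vehicle replicate 1 (0.0841) or RS4:11 3xEC50 replicate 2 (0.0915). The NF-kappaB call at EC50 was lost without RS4:11 EC50 replicate 1 (0.209), SEM-K2 EC50 replicate 1 (0.0672) or RS4:11 vehicle replicate 2 (0.0593). Without _x_at probe sets the metallothioneins had a median difference of 0.23 at 3xEC50 (adjusted p = 0.809). The count of 4 genes at 3xEC50 became 20 without SEM-K2 3xEC50 replicate 1, 2 without SEM-K2 vehicle replicate 2, and 1 without either RS4:11 3xEC50 array or RS4:11 vehicle replicate 2. The count of 1 at EC50 became 4 without SEM-K2 EC50 replicate 1 and 2 without SEM-K2 EC50 replicate 2 or either SEM-K2 3xEC50 array. KANK1 stayed called without any 1 array. The call on DLX2 was lost with trend and robust settings (adjusted p = 0.0919), and without any vehicle array or either RS4:11 3xEC50 array. That on CD1A was lost without either RS4:11 vehicle or 3xEC50 array, and that on ENPP2 without 9 of the 12 arrays, with SEM-K2 EC50 replicates 1 and 2 and SEM-K2 3xEC50 replicate 1 as the exceptions. Of the calls that held, some medians moved by over 1.5 times. At EC50 these were chaperones without SEM-K2 vehicle replicate 1 (0.32) and NF-kappaB targets without SEM-K2 vehicle replicate 2 (0.26). At 3xEC50 they were NF-kappaB targets (0.71) and oxidative phosphorylation (-0.18) without SEM-K2 vehicle replicate 2, and lysosome (0.45) and cholesterol genes (0.61) without SEM-K2 vehicle replicate 1. Cholesterol genes also had 0.54 without RS4:11 3xEC50 replicate 1 and 0.55 without SEM-K2 3xEC50 replicate 2, where oxidative phosphorylation had -0.16.

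As sets, the genes that changed in SEM-K2 shifted the same way in RS4:11. Of the 66 genes that rose in SEM-K2 at 3xEC50, 58 lay above 0 in RS4:11 at that dose, with a median of 0.35 against 1.45 in SEM-K2, where they were chosen. As a set they shifted up in RS4:11 (camera p = 1.17e-20, p = 0.00633 with an estimated correlation). Of the 21 that fell, 17 lay below 0 in RS4:11, with a median of -0.29 against -1.31 (camera p = 9.01e-09, p = 0.0146 with an estimated correlation). Adjusted over each set alone, 23 of the 66 rose and 2 of the 21 fell in RS4:11. PTPRE (1.27), GPR18 (1.45), TNFAIP3 (1.36) and KLHL14 (-1.05) showed large values there without passing over all genes. The largest was in USP18, a brake on interferon signalling chosen after its values were seen, with 2.66 ± 0.40 in RS4:11 (adjusted p = 0.245), at least 6.03-fold from below the floor, and 2.30 in SEM-K2. The lines share no control arrays, and their changes at 3xEC50 correlated at r = 0.405 across genes. Changes taken from 1 array per group, which are noisier, gave r of 0.342 and 0.280 with equal replicate numbers. With crossed numbers, which share no pairing, such changes gave 0.316 and 0.244. The correlation was 0.241 without SEM-K2 3xEC50 replicate 1 and 0.269 without SEM-K2 vehicle replicate 2. At EC50 r was 0.432. Changes taken from 1 array per group gave 0.305 and 0.372 there with equal replicate numbers, and 0.257 and 0.208 with crossed ones.

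**Figure D4:**
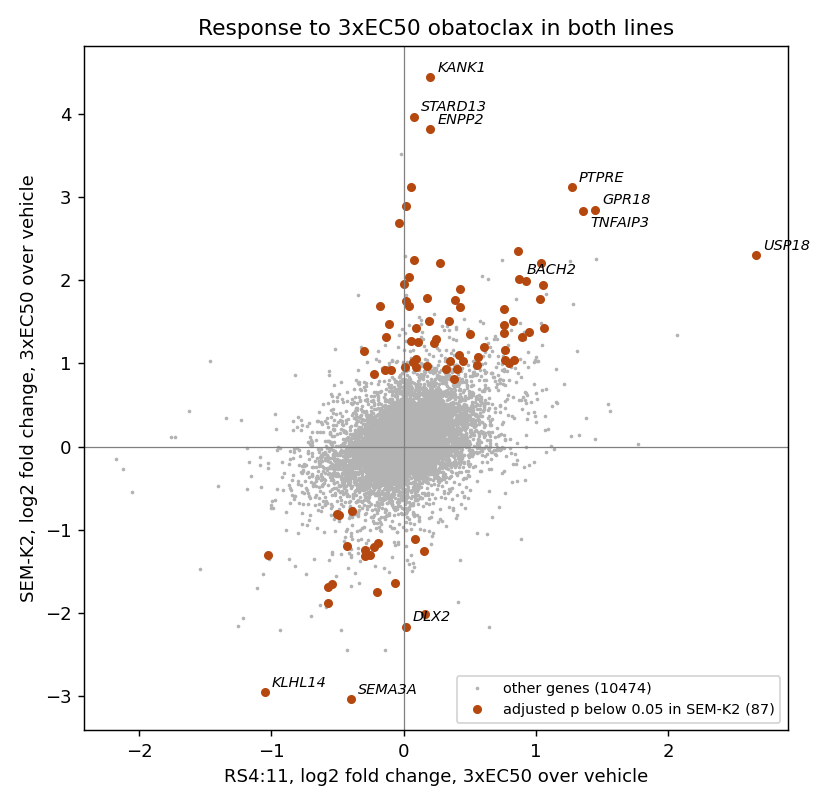
Log2 change at 3xEC50 against vehicle in RS4:11 (x axis) and SEM-K2 (y axis), 1 point per gene. The 87 genes called in SEM-K2 are coloured and the others grey; across all genes r was 0.405.

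The comparison of the vehicle-treated lines asks how they differed before any drug. LAPTM4B, a lysosomal transmembrane protein gene, reached 13.06 ± 0.02 in SEM-K2 and 2.46 ± 0.04 in RS4:11 (log2, SD, n = 2), at least 532-fold higher. The hormone gene PRL, prolactin, was at 12.70 ± 0.02 in RS4:11 and 2.60 ± 0.55 in SEM-K2, at least 415-fold higher in RS4:11. B cell precursor markers were lower in SEM-K2, with a median difference of -2.75 and 18 of 22 members called over all genes (camera adjusted p = 4.69e-13, adjusted p = 0.213 with an estimated correlation). In all, 1060 genes were higher in SEM-K2 and 1014 in RS4:11, 1350 of the 2074 by at least 2-fold.

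After LAPTM4B (10.59 ± 0.13, adjusted p = 1.44e-10), the largest log2 differences towards SEM-K2 were in the guidance receptor gene ROBO1 (9.16), the pseudokinase gene TRIB2 (8.83), BEND4 (8.03), GOLGA8A (7.91) and the peroxidase gene PXDN (7.89). These were at least 239-fold, 109-fold, 80.1-fold, 76.9-fold and 72.7-fold higher in SEM-K2. After PRL (-10.10 ± 0.37, adjusted p = 7.59e-08), the largest log2 differences towards RS4:11 were in GTSF1 (-9.44), TNFSF4, the OX40 ligand gene (-7.57), the arginine synthesis gene ASS1 (-7.56), the extracellular matrix gene EFEMP1 (-7.49) and NRN1 (-7.47). These were at least 191-fold, 82.1-fold, 67.2-fold, 61.0-fold and 51.5-fold higher in RS4:11. Counted from the floor, LAPTM4B and ROBO1, and PRL and GTSF1, kept ranks 1 and 2 of their direction, and the others ranked 4 to 10 and 5 to 10. All 12 of these calls held without any 1 array. With an estimated correlation, camera passed B cell precursor markers when that fit held the replicate block (adjusted p = 0.0480). RAG1, which recombines antigen receptor genes and lay below the floor in SEM-K2, was at least 39.8-fold higher in RS4:11, and the surrogate light chain gene VPREB1 differed by -3.15. Adjusted over the list alone, 19 members differed. Metallothioneins were lower in SEM-K2 (median -1.69, adjusted p = 2.32e-04, adjusted p = 0.337 with an estimated correlation), but without _x_at probe sets their median was 0.50 (adjusted p = 0.494). Hypoxia and glycolysis genes were higher in SEM-K2 (26 of 29 above 0, median 0.53, adjusted p = 0.0387, adjusted p = 0.903 with an estimated correlation). That call was lost without SEM-K2 vehicle replicate 1 (0.285) or RS4:11 vehicle replicate 2 (0.228). KMT2A (-0.94 ± 0.25, adjusted p = 0.0252) and AFF1 (-0.91 ± 0.17, adjusted p = 0.0043) were lower in SEM-K2, and whether their probe sets match the fusion transcript was not examined.

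The BCL2 family genes fixed beforehand did not pass in either line. In SEM-K2 at 3xEC50 the changes were, for the antiapoptotic genes, BCL2 (0.33 ± 0.13, adjusted p = 0.363), BCL2L2 (0.43 ± 0.22, adjusted p = 0.492), BCL2L1 (-0.72 ± 0.72, adjusted p = 0.762) and MCL1 (0.16 ± 0.17, adjusted p = 0.776). For the effector genes they were BAX (-0.99 ± 0.70, adjusted p = 0.644) and BAK1 (-0.31 ± 0.25, adjusted p = 0.697). The probe sets of MCL1 ranged from -1.59 to 0.16 and those of BCL2L1 from -0.72 to 0.55. In RS4:11 at 3xEC50 BCL2L1 showed 0.72, BCL2 0.18, and the other 4 genes from 0.00 to 0.06. As lists, antiapoptotic genes had medians of 0.11 in RS4:11 and 0.24 in SEM-K2 at 3xEC50 (adjusted p = 0.458 and 0.455), and proapoptotic genes 0.05 and -0.04 (adjusted p = 0.905 and 0.455). The proapoptotic BH3-only genes BIK in RS4:11 (1.14 ± 0.44, adjusted p = 0.895) and BCL2L11 in SEM-K2 (0.67 ± 0.25, adjusted p = 0.343) had the smallest p of their list.

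The remaining lists did not pass at 3xEC50 in either line with all arrays. With 1 array left out, DNA replication passed in RS4:11 (without 3xEC50 replicate 1 or vehicle replicate 2) and SEM-K2 (without vehicle replicate 2). Oxidative phosphorylation passed in RS4:11 (without the same arrays) and SEM-K2 (without 3xEC50 replicate 2), and immediate early genes in SEM-K2 (without vehicle replicate 1). Over all 30 lists, 8 and 7 combinations of a list and an omitted array passed at 3xEC50 in RS4:11 and SEM-K2 where the list did not with all arrays. There were 5 and 11 at EC50, 16 and 18 in the differences between lines at EC50 and 3xEC50, and 3 between vehicles. Their medians, RS4:11 before SEM-K2, were -0.01 and 0.02 for caspases and death receptors (adjusted p = 0.533 and 0.983), 0.07 and 0.23 for necroptosis (0.503 and 0.455), 0.00 and 0.11 for the mTOR pathway (0.805 and 0.983), -0.02 and -0.10 for p53 targets (0.503 and 0.350), and -0.01 and -0.06 for the NRF2 response (0.315 and 0.983). Fatty acid synthesis had -0.09 and 0.13 (0.199 and 0.695), immediate early genes 0.02 and 0.42 (0.859 and 0.155), ribosomal proteins 0.04 and 0.04 (0.327 and 0.983), DNA replication 0.10 and 0.12 (0.166 and 0.730), oxidative phosphorylation 0.06 and -0.02 (0.0633 and 0.300) and MLL fusion targets -0.02 and -0.01 (0.905 and 0.983). Among markers of other cell types, medians were 0.28 and 0.51 over 5 myeloid genes (0.219 and 0.629), 0.02 and 0.25 over 4 T and NK cell genes (0.859 and 0.983), -0.01 and -0.08 for 1 erythroid and megakaryocyte gene (0.938 and 0.798), and 0.07 and -0.15 over 3 fibroblast and epithelial genes (0.503 and 0.455). The test and the median differed in sign in SEM-K2 for caspases, ribosomal proteins, T and NK cell genes and MLL fusion targets, and in RS4:11 for MLL fusion targets, the mTOR pathway and T and NK cell genes. With another median or quantile scaling, the sign of the median turned in RS4:11 or SEM-K2 at 3xEC50 for proapoptotic genes, caspases, the mTOR pathway, immediate early genes, ribosomal proteins, T and NK cell genes and the erythroid and megakaryocyte gene, none of them past the test. The mean of the NRF2 response (0.06) and of MLL fusion targets (0.09) in SEM-K2 differed in sign from the median, as did in RS4:11 those of the mTOR pathway, T and NK cell genes and cholesterol genes. Adjusted over their lists alone, the necroptosis gene CYLD, a deubiquitinase (0.80), and the fatty acid genes ACSL1 (0.79) and ACSS2 (0.73) rose in SEM-K2, EYA1 rose in SEM-K2 (1.02), and SLC7A11 fell in RS4:11 on the NRF2 list. CDKN1A, the p53 target p21, had 0.90 ± 0.26 in SEM-K2 (adjusted p = 0.224) and the glycolytic gene ENO2 2.29 ± 0.56 (adjusted p = 0.146).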

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

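The tests of single genes between the lines, and of lists at 3xEC50, were planned. The list tests at EC50, the tests of a hidden fall and of single RS4:11 vehicle arrays, and the ratio of replicate spreads were chosen after the result was seen.

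Integrated stress response genes differed between the lines by a median of 0.50 at 3xEC50 and 0.41 at EC50. They fell in RS4:11 at the preset correlation, but at 3xEC50 not past the threshold with an estimated correlation. In SEM-K2 the whole list did not shift, though its amino acid supply genes had a median of -0.17 at 3xEC50. If SEM-K2 3xEC50 replicate 2, with its high 3' to 5' differences, had hidden a fall in SEM-K2, the EC50 difference, which does not use that array, would lie near 0, but it was 0.410 with 34 of 36 genes above 0. A single RS4:11 vehicle array did not carry the fall, as the weaker median without one of them was -0.480, nor did a single replicate set, as the weaker median within one was -0.466. Both doses share the 2 RS4:11 vehicle arrays, so an offset common to both arrays was not tested and stays open. A biological difference between the lines stays open too, as do unequal concentrations behind equal multiples of the EC50. Unequal concentrations may also be the source and were not tested, as the doses were not given in the sources used here. The p of the difference was 0.213 at 3xEC50 and 0.118 at EC50 with an estimated correlation, so this remains a hypothesis.

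Limma called 87 genes in SEM-K2 and 0 in RS4:11 at 3xEC50, with 1233 and 518 at an unadjusted p under 0.05. With the replicate block over all arrays it called 220 and 0, with 1848 and 1031 at an unadjusted p under 0.05. The ratio of pooled SDs between replicates was 0.944 for RS4:11 over SEM-K2, where SEM-K2 at 3xEC50 had the largest SD (0.512). As all arrays shared 1 estimate of the spread, both lines had the same SE per gene. A larger spread between RS4:11 replicates would have raised the SE of both lines alike, so the ratio cannot weigh it as the cause. The shared SE may be too small for SEM-K2 at 3xEC50, the group with the largest SD, so calls there may be too many. Against the SEM-K2 array with the high 3' to 5' differences as the whole cause stands the covariance between the changes of replicates 1 and 2. The error of 1 array does not add to this covariance, but a bias shared by both replicates would. In SEM-K2 replicate 1 the ACTB difference was 1.11 at 3xEC50 and 1.02 in vehicle. This covariance was 2.00 times as large in SEM-K2 as in RS4:11 (95% interval 1.77 to 2.25 over 200 draws of genes, which are not independent), yet without that array 18 genes were called, against 87. How far a larger response of SEM-K2, a biological explanation, holds at EC50 as well is left open, as the ratio there was 1.35 (1.15 to 1.55), above 1 but with an interval that reached past both bounds set beforehand, and the concentrations are unknown.

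Among single genes, the response of KANK1 differed between the lines by 3.92 at EC50 and by 4.24 at 3xEC50, sizes that rest on values below the floor in RS4:11 and in SEM-K2 vehicle. That of ENPP2 differed by 3.62 at 3xEC50, with the same limit. That of CD1A differed by 3.06 at 3xEC50, with the same limit. That of DLX2 differed by -2.18 at 3xEC50, with all RS4:11 arrays below the floor, where a fall could not show. The list differences that follow passed at the preset correlation, and none passed with an estimated correlation. Endoplasmic reticulum chaperones differed by a median of 0.21 at EC50 and 0.27 at 3xEC50 (adjusted p = 0.118 and 0.222 with an estimated correlation). NF-kappaB targets differed by 0.58 at EC50 and 1.08 at 3xEC50 (0.181 and 0.213). At 3xEC50, cholesterol genes differed by 0.36 (0.833), lysosome genes by 0.28 (0.273), metallothioneins by -0.38 (0.262) and oxidative phosphorylation genes by -0.0849 (0.833). Without SEM-K2 3xEC50 replicate 1 these 6 calls at 3xEC50 were lost (adjusted p from 0.130 to 0.695), and without _x_at probe sets the metallothioneins had 0.23. Outside the named genes, 7 probe sets without exactly 1 gene symbol changed in SEM-K2 at 3xEC50 (3 up and 4 down), of 74 probe sets called when 24865 were tested, 4534 of them without exactly 1 symbol.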

How the results depend on the processing

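All alternatives were planned, and the list differences at EC50 to which some were applied were added later. Of 41 list calls and 53 calls on named genes, a further median or quantile scaling ended none. Of the list calls, 3 held with an estimated correlation (stress response and chaperones in RS4:11 at EC50, chaperones at 3xEC50), none of them when that fit also held the replicate block (adjusted p = 0.124, 0.0961 and 0.0918), 10 under fry, 35 with the mean of probe sets, 32 without a floor, 39 with a floor of 6 and 37 without _x_at probe sets. Of the calls on named genes, 50 held with trend and robust settings, 51 without _x_at probe sets, 30 of 44 with the mean of probe sets, and 16 with only the arrays compared, a fit with fewer residual degrees of freedom. With each array left out in turn, the one left alone in its group was assumed to vary like the other groups, and 450 of 492 list calls and 437 of 636 calls on named genes held. Values below the floor limit folds: all arrays of SEM-K2 vehicle lay below it for 13 of the 66 genes that rose at 3xEC50, and those of 1 line for 291 and 158 of the genes higher in the other. Where no cause is given, the cause was not tested.

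The replicate block over all arrays gave 46 genes in SEM-K2 at EC50 (18 without it) and 220 at 3xEC50 (87 without it). The replicate block within each line gave 70 and 299, and 2 and 7 genes whose responses differed between the lines at EC50 and 3xEC50 (1 and 4 without it). Apart from the single genes added to these counts and the changes of call printed in the report beside each result, the replicate block over all arrays changed no other call at the preset correlation. The replicate block within each line ended 2 of the 41 list calls. Without a floor, 2 genes were called in RS4:11 at EC50, 8 in SEM-K2 at EC50, 2 between doses in RS4:11, 3 between doses in SEM-K2 and 2 in the difference at EC50. With a floor of 6, 2 were called in each difference between lines and the correlation of the lines at 3xEC50 was 0.451 (0.405 with the floor of 4). Quantile scaling gave 1 gene between doses in SEM-K2 and 2 in the difference at EC50. The mean of probe sets gave 1 gene in RS4:11 at each dose, 11 in SEM-K2 at EC50, 44 at 3xEC50 and 2 in the difference at EC50. Every probe set on its own gave 1 in RS4:11 at EC50, 4 at 3xEC50, 3 in the difference at EC50 and 3547 between vehicles. Only the arrays compared, with fewer residual degrees of freedom, gave 1 in SEM-K2 at EC50, 0 by limma at 3xEC50, where 681 had an unadjusted p under 0.05, 2 in the difference at EC50 and 1319 between vehicles. At an adjusted p under 0.01, a stricter threshold, 4 and 24 genes were left in SEM-K2 at EC50 and 3xEC50, 1 in the difference at 3xEC50 and 1261 between vehicles, where a 2-fold minimum left 1350.

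With 1 array left out, counts ranged from 0 to 3 in RS4:11 at EC50, 0 to 1 at 3xEC50 and 0 to 0 between doses. They ranged from 3 to 17 in SEM-K2 at EC50, 14 to 169 at 3xEC50 and 0 to 36 between doses, from 1 to 4 and 1 to 20 in the differences at EC50 and 3xEC50, and from 1419 to 2100 between vehicles. The correlation of the lines at 3xEC50 ranged from 0.241 to 0.472. Mitosis genes changed direction with 1 array left out: their median ranged from -0.23 to 0.72 in RS4:11 at EC50, from -0.19 to 0.73 at 3xEC50, from -0.59 to 0.36 in the difference at EC50 and from -0.61 to 0.33 in that at 3xEC50, each time with RS4:11 vehicle replicate 1 or 2 left out. Their median in RS4:11 at 3xEC50 was -0.01 without 3xEC50 replicate 1. Ribosome biogenesis genes ranged from -0.11 to 0.21 in the difference at EC50. Without _x_at probe sets, metallothioneins had 0.23 in the difference at 3xEC50 and 0.50 between vehicles. Ribosomal proteins in SEM-K2 at 3xEC50 passed upwards without a floor (median 0.0368, adjusted p = 0.0206), and heat shock genes passed between vehicles under fry (median -0.19, adjusted p = 0.0286), against the direction camera gave.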

Other observations

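The tests of further lysosome genes, of amino acid supply genes, of stress effectors and of FOXO targets were chosen after the first results were seen, as were the genes of the next paragraph.

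Of the 87 genes called in SEM-K2 at 3xEC50, 11 were on a list fixed beforehand, and the others, not tested for enrichment, include genes of B cells and of lysosomes. The B cell surface genes MS4A1, which encodes CD20, and CD40 rose by 2.25 ± 0.22 and 2.21 ± 0.25 on the log2 scale. The lysosomal sialic acid exporter gene SLC17A5 (1.95 ± 0.21), the trafficking regulator gene LYST (1.69 ± 0.25), the ganglioside activator gene GM2A (1.32 ± 0.23) and the acid ceramidase gene ASAH1 (0.97 ± 0.14) also rose. GSDME, a gasdermin that caspases can cleave, rose by 2.21 ± 0.17 and USP18, a brake on interferon signalling, by 2.30 ± 0.40. The interleukin 7 receptor gene IL7R fell by 1.31 ± 0.16.

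In RS4:11 at 3xEC50 the genes of the integrated stress response list that supply amino acids or charge transfer RNAs had a median of -0.55, and in SEM-K2 of -0.17. No p is given for RS4:11, since these genes were picked from a list already seen to fall there. In SEM-K2, where 5 of 23 measured genes lay above 0, they shifted down at the preset correlation (camera p = 0.00143). With an estimated correlation camera gave p = 0.165.

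One hypothesis was that lysosome genes at large respond, beyond the list fixed beforehand. The 36 measured members of a further lysosome list, without genes called in SEM-K2, had a median of 0.130 in RS4:11 at 3xEC50, 26 of them above 0. Their p was 0.0171, but 0.261 with an estimated correlation, so a response of the whole compartment may exist and is left undecided. Another was that stress effectors rise in SEM-K2 while amino acid supply genes do not. The 8 measured effectors, among them DDIT3, PPP1R15A and ATF3, had a median of 0.473 with 6 above 0 (p = 0.00317, p = 0.164 with an estimated correlation), and DDIT3 and PPP1R15A had been seen to rise before, which leaves it undecided too. The last was that FOXO targets rise together in both lines. RAG1, IRS2 and genes called in SEM-K2 were left out of this list. In RS4:11 the 16 measured targets that remained had a median of 0.207 with 13 above 0 (p = 3.53e-04, p = 0.157 with an estimated correlation). In SEM-K2 their median was 0.232 with 12 above 0, but the camera p was 0.181, so the prediction was not met. As genes called in SEM-K2 were left out, the test there does not cover the FOXO targets that changed most clearly. The lists of this part made 24 tests over 6 contrasts. Adjusted over them, the p-values quoted as 0.00143, 0.0171, 0.00317 and 3.53e-04 became 0.00262, 0.0228, 0.00448 and 0.00103. With an estimated correlation they became 0.257, 0.340, 0.257 and 0.257.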
